A study of Homo sapiens with 8 samples.

How the data were processed

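RNA from MOLM-13, a human acute myeloid leukemia cell line, was sequenced in bulk with a TruSeq RNA kit on an Illumina HiSeq instrument, per the labels' protocols. The labels describe 8 samples. The 4 libraries analysed here are parental replicate 2 and the vehicle (DMSO) cultures after treatment courses 1, 3 and 5, with 1 library for each. The 3 busulfan libraries and parental replicate 1 were not analysed here. Per the labels, busulfan was given for 6 h at 25 to 200 µM in 5 courses, and control cells were prepared in parallel with 1% DMSO. The labels give at most 20 passages for the parental cells and at most 60 for the busulfan-resistant cells. For the DMSO cultures they give no passage number, so passage cannot be separated from the courses.

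The deposited values are raw read counts per Ensembl gene ID, with 5 HTSeq summary rows in each file. FastQC 0.11.5, TopHat2 2.0.11, HTSeq 0.6p1 and the build hg19 are named in the submitters' processing notes. All 58735 gene IDs of the deposited count files matched GENCODE release 29, which is annotated on GRCh38 and not on hg19, so the build behind the counts is uncertain. No coordinates of single genes are given, and GENCODE release 29 positions were used only for a region of chromosome 6 and for the distance between neighbouring genes. Reads were counted as reverse-stranded, as far as the deposited files' names tell. Gene symbols and types were taken from GENCODE release 29. Reads aligned to several places are held in a summary row and not in any gene, so genes with near-identical copies are undercounted or uncertain.

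Summary rows were left out of library sizes and tests. They held 24.95% of the reads in the parental library, 27.14% in DMSO course 1, 24.57% in course 3 and 29.81% in course 5. Gene counts totalled 56825811 in the parental library and 44795976, 50855326 and 45095954 in DMSO courses 1, 3 and 5. No 2 libraries agreed within counting noise, so each was used as its own sample.

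Counts were analysed in R 4.3.3 with edgeR 4.0.16, limma 3.58.1 and DESeq2 1.42.0. CPM, the deposited counts scaled to a common library size, was computed with TMM-scaled library sizes. Genes were kept for tests with edgeR's filterByExpr (minimum count 10, minimum total 15), which left 18612 genes. The pooled comparison set the 3 DMSO libraries against the parental library with edgeR's quasi-likelihood test and Benjamini-Hochberg adjusted p under 0.05. The trend tested a slope over 0, 1, 3 and 5 courses in the same way. Both fits had 2 residual degrees of freedom. In the pooled fit the spread came from DMSO libraries of different courses, and the lone parental library was assumed to vary like them. Nothing in the labels says that the libraries are replicate cultures of one state, so these p-values measure only the spread between these libraries.

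Single libraries were compared without a test, as log2 ratios of CPM with exact binomial 95% intervals that cover counting error only. A gene was counted as apart when its mean was at least 5 CPM (10710 genes), the ratio was at least 2-fold and the interval excluded a ratio of 1. A count of 0 was set to a floor of 3 counts per library, which gives a bound. Distances between libraries were the SD over genes of the log2 CPM difference (prior count 2) and Spearman's correlation across genes, which are not independent replicates.

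The 30 gene lists, 4 of them markers of other cell types, were written before the data were examined, as were the tests, the rule for named genes and all alternatives but the rescaling of the named genes and the entry of fry as an alternative. Lists were tested with limma's camera on log2 CPM at a preset correlation of 0.01, adjusted over the lists, with an estimated correlation and with fry's directional and mixed tests beside it. For single libraries the list's median log2 ratio was placed among 10000 random lists of the same size matched on mean expression. Symbols were matched to GENCODE names and, for older names, to RefSeq synonyms. GSTT1 was the 1 symbol without a match. A list of translation factors was added after the data had been seen.

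Named genes followed a fixed rule. For the pooled comparison up to 12 genes in each direction were named, and since no gene passed the test they were those at least 2-fold apart in all 3 DMSO libraries, ranked by the smallest of the 3 ratios. For the trend they were up to 8 genes in each direction in strict order, ranked by the smallest step. For each library they were up to 5 genes in each direction at least 2-fold apart from every other library, and for each list up to 4 members with the largest pooled fold change. Clone-named genes, small RNAs, numbered pseudogenes and Y-linked genes were counted and not named. Some genes that the rule selects are not reported here.

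The functions were tested on simulated counts for the 18612 genes with 200 changed genes. At a dispersion of 0.1 the pooled test recovered 43 of 100 genes changed 4-fold and 91 of 100 changed 16-fold, with 4 false calls. The trend recovered 25 of 100 changed 4-fold over 5 courses and 92 of 100 changed 16-fold, with 4 false calls. All simulated genes had the same dispersion, while genes of the real libraries differed in spread. The recovery rates therefore need not hold for the real libraries, where a lack of calls does not show that such changes are absent. The counting interval held the true ratio in 95.6% of 18612 simulated genes. Alternatives were RLE size factors, total CPM, DESeq2's Wald test, limma-voom, other filters and fold minimums, a slope per rank, and leaving out each library in turn.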

Results

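The study addressed how a leukemia line acquires resistance to the alkylating agent busulfan, with mitochondrial copy number and lipid and cholesterol metabolism as its themes. The libraries analysed here are its drug-free arm. MOLM-13 cells before any treatment (parental, 1 library) were set beside cells carried through 1, 3 or 5 courses of the vehicle DMSO at 1% (1 library each). The question these libraries answer is how far expression differed from the parental cells in cultures that never met the drug. The parental library held 56825811 gene counts, DMSO course 1 held 44795976, course 3 held 50855326 and course 5 held 45095954. No library has a replicate at its own course.

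DMSO courses 3 and 5 were close to each other, and course 1 was farther from course 5 than either was from the parental cells. Over 10710 genes with a mean of at least 5 CPM, the SD of the log2 difference was 0.30 between courses 3 and 5 and 0.83 between courses 1 and 5. It was 0.61, 0.53 and 0.69 between the parental library and courses 1, 3 and 5, and 0.62 between courses 1 and 3. Spearman's correlation across genes ran from 0.892 for courses 1 and 5 to 0.987 for courses 3 and 5. Genes at least 2-fold apart numbered 1738 between courses 1 and 5 and 106 between courses 3 and 5. The vehicle libraries therefore spanned a wider range among themselves than the distance of any of them from the parental library.

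**Figure D1:**
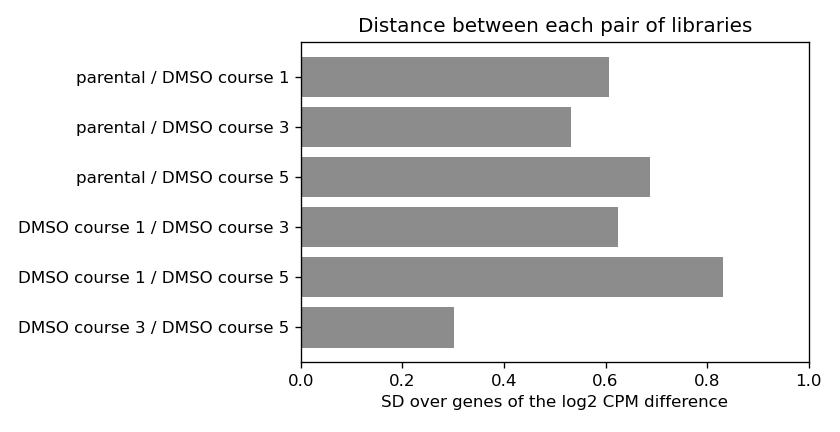
Horizontal bars give, for each pair of libraries, the SD over 10710 genes of the log2 CPM difference (horizontal axis, from 0). The shortest bar is that of DMSO courses 3 and 5 (0.30) and the longest that of courses 1 and 5 (0.83).

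The pooled comparison asked which genes separated all 3 DMSO libraries from the parental cells. The gene lowest in the DMSO libraries was CDX2 (ENSG00000165556), an intestinal homeobox factor that is also expressed in many acute myeloid leukemias. It stood at 108.2 CPM (6400 counts) in the parental library, 1.11 CPM (48 counts) in course 1, 0.119 CPM (6 counts) in course 3 and 0 counts in course 5. The log2 ratio of CDX2 to the parental library was -6.60 in course 1 (95% counting interval -7.04 to -6.19) and -9.82 in course 3 (-11.27 to -8.70), and the floor of 3 counts put it at -10.68 or lower in course 5. A second homeobox gene, BARX1, stood at 87.6 CPM in the parental library and at 2.44, 0.936 and 0.198 CPM in courses 1, 3 and 5. Among the others, the natriuretic peptide receptor gene NPR3 had log2 ratios of -4.93, -5.27 and -4.83, the cadherin-family gene FAT1 with -4.25, -5.01 and -6.01, the neuropilin NRP2 with -4.80, -3.73 and -4.62, and the tetraspanin CD9 with -3.31, -4.93 and -5.05. WWC2, HOMER2, IL12A-AS1, EPB41L2, CAMKV and C3orf80 completed the 12 genes of that direction. The ratio nearest to the parental level among these genes was that of C3orf80 in course 5, at -3.21.

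**Figure D2:**
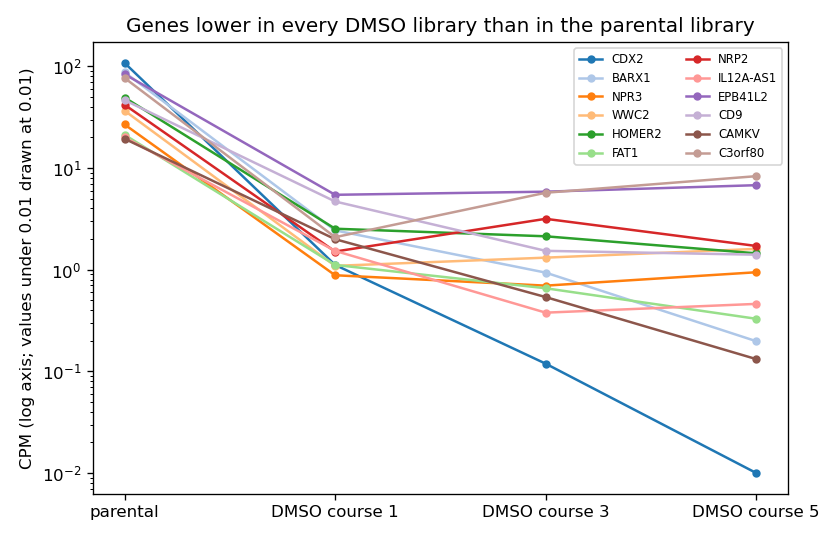
CPM on a log axis for the 12 genes lower in every DMSO library, with 1 point per library and lines joining the points of a gene. CDX2 is at 108.2 CPM in the parental library and, at 0 counts in course 5, is drawn at 0.01. EPB41L2 is at 83.8 CPM in the parental library and between 5.46 and 6.78 CPM in the DMSO libraries.

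In the other direction ADAMTS7, which encodes a secreted metalloprotease, stood at 0.389 CPM (23 counts) in the parental library and at 8.94, 15.5 and 13.6 CPM in courses 1, 3 and 5. RHOBTB3 was at 10.97 CPM in the parental library and at 103.7, 98.3 and 97.7 CPM in the DMSO libraries. The transcription factor genes HNF4G (1.88 CPM in the parental library, 36.6 CPM in course 5) and FOXP2 (0.913 CPM and 18.6 CPM) were higher in each DMSO library too. C8orf88, CAMSAP3, ALPK3, TRDC, ZNF525, ZNF610, SLC6A12 and the tryptase gene TPSAB1, which has a near-identical neighbour and is uncertain for that reason, made up the 12. GATA2, a regulator of blood progenitors, was at 88.1 CPM in the parental library and at 280.8, 370.0 and 338.9 CPM in courses 1, 3 and 5.

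None of these genes passed the test. Of 18612 genes, edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment called 0, and limma-voom also called 0, while DESeq2's Wald test called 209. At an unadjusted p under 0.05 edgeR listed 1045 genes, where chance alone gives 931. The same fit with course 1, 3 or 5 as the lone library listed 2964, 43 and 787 and also called 0 each, so by this count course 1 and not the parental library stood most apart. The smallest adjusted p was 0.109 in edgeR, shared by NPR3 (log2 fold change -4.99, SE 0.307), WWC2 (-4.78, SE 0.310) and EPB41L2 (-3.80, SE 0.233). CDX2 had a fitted log2 fold change of -8.06 with SE 1.47. The count hung on single libraries: without course 1, 1578 genes passed (625 higher, 953 lower), without course 3 it was 25 and without course 5 it was 31, each with 1 residual degree of freedom.

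Each DMSO library was also set against the parental library on its own, with no test. Course 1 had 396 genes at least 2-fold higher and 449 lower, course 3 had 239 and 251, and course 5 had 317 and 527. With total CPM, which leaves out composition scaling, the course 1 split was 283 higher and 664 lower, and all its log2 ratios shifted by -0.114. All 3 libraries shared 93 higher and 65 lower genes, courses 3 and 5 shared 199 and 235, and courses 1 and 5 shared 96 and 70. Independent lists would share 7.1 and 12.4 for courses 3 and 5, and 11.7 and 22.1 for courses 1 and 5. Libraries with no difference but a dispersion of 0.115, set against the same parental library, shared 169 higher and 71.1 lower genes across all 3 on average in 100 simulations, 314.1 and 196.9 for courses 3 and 5 (235 lower genes at most), and 312.7 and 195.1 for courses 1 and 5. With only 1 parental library that control could not be split, so part of the sharing may come from it. The simulation gave every gene the same dispersion, the median of the pooled fit, and the lengths of its lists were not recorded. Its counts therefore cannot be set against the observed ones as more or less sharing. It also drew all 3 courses from the same mean per gene, so the 2 pairs of courses had to share nearly equally. The simulation therefore says nothing on the difference between the pairs. In the opposite direction, 68 genes were higher in course 1 and lower in course 5, and 29 were lower in course 1 and higher in course 5.

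Among genes that could be named, with a mean of at least 5 CPM, 148 were at least 2-fold higher and 194 at least 2-fold lower in course 1 than in every other library. CHAC1, a glutathione-degrading enzyme induced by ATF4, was at 0.302 CPM (13 counts) in course 1 against 15.7 CPM in the parental library, 49.9 CPM in course 3 and 51.6 CPM in course 5. PSAT1, of serine synthesis, was at 23.8 CPM in course 1 and at 212.2, 332.5 and 438.0 CPM in the parental, course 3 and course 5 libraries. The glycine transporter gene SLC6A9 had 1 count in course 1 and 231, 314 and 461 in those libraries, and INHBE had 2 counts against 158, 459 and 419. G0S2 was lowest in course 1 as well. The enolase gene ENO2 was at 355.4 CPM in course 1 and at 90.6, 63.1 and 17.1 CPM in the parental, course 3 and course 5 libraries, and ADM, encoding adrenomedullin, was at 21.9 CPM against 5.48, 1.16 and 0.505 CPM. TBC1D30, RGS16 and PTGDS were also highest in course 1.

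Course 5 was lowest in PNCK (1.84 CPM against 96.2 in the parental library and 216.8 in course 1), in the creatine transporter gene SLC6A8 (4.43 CPM against 82.4 and 217.9) and in SH3D21 (0.834 CPM against 28.9 and 69.3). It was highest in CYFIP2, RPS6KA2, KDM7A, CADM1 and ATF5, a stress-induced transcription factor gene at 217.4 CPM in course 5 and 49.3 CPM in the parental library. In course 3, 1 such gene was at least 2-fold higher than in every other library and 0 were lower. This was the early-response gene FOSB, at 30.7 CPM in course 3 and at 5.61, 6.36 and 9.44 CPM in the parental, course 1 and course 5 libraries. EGR1, of the immediate early list, was at 243.8 CPM in course 3 against 89.8, 141.5 and 119.5 CPM.

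The trend asked which genes followed the number of courses. SPP1, encoding osteopontin, stood at 16.5, 5.87 and 0.299 CPM after 0, 1 and 3 courses and at 0 counts after 5. The kinesin gene KIFC3 stood at 48.9, 24.4, 7.91 and 3.31 CPM, and the Fc receptor genes FCGR2B (31.0, 12.3, 0.757 and 0.154 CPM) and FCGR2C (48.2, 12.2, 1.16 and 0.439 CPM) with the neighbouring HSPA7 went the same way, although these paralogous and overlapping genes share reads and are uncertain as single genes. CAMKV, BARX1 and MXRA8 also stood in falling order. In rising order were the kinase gene PLK2 (4.35, 6.94, 10.7 and 18.2 CPM), TKTL1 (2.50, 12.7, 19.1 and 32.4 CPM), the nuclear receptor corepressor gene NRIP1 (1.17, 1.81, 8.52 and 12.9 CPM), CNKSR3, DUSP16, GATM, KLF5 and DZIP1. Among genes with a name and a mean of at least 5 CPM, 828 were in strictly rising and 637 in strictly falling order. Steps of any size counted, also those within counting error, and some genes fall in order by chance. These counts alone therefore do not show that expression followed the courses.

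No slope passed the test. edgeR's quasi-likelihood test called 0 of 18612 genes after Benjamini-Hochberg adjustment, limma-voom called 0 and DESeq2's Wald test called 888. At an unadjusted p under 0.05 edgeR listed 2940 genes (1141 rising, 1799 falling). The smallest adjusted p in edgeR was 0.0713, for SPP1 (slope -2.04 log2 units per course), FCGR2B (-1.64), HSPA7 (-1.52) and KIFC3 (-0.77). Without course 1 the count was 2795 genes, without course 3 it was 32, without course 5 it was 5, and over the DMSO courses alone, without the parental library, it was 3642, each with 1 residual degree of freedom. Of the 12 orderings of the 4 libraries, the order course 1, parental, course 3, course 5 called 184 genes, and each of the other 11, the real order among them, called 0.

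The gene lists on the study's themes did not move as one with the courses. Cholesterol synthesis genes were lower with more courses in the trend (camera, adjusted p = 0.000101 at the preset correlation), with 2 of 20 members past the slope test adjusted over the list alone and 0 over all genes. Adjusted p = 0.717 with an estimated correlation. The list's median log2 ratio to the parental library was 0.32 in course 1, -0.49 in course 3 and -0.69 in course 5, so its sign differed between courses. The farnesyl diphosphate synthase gene FDPS was at 186.6, 222.0, 110.1 and 89.8 CPM after 0, 1, 3 and 5 courses, ACAT2 at 55.0, 52.1, 24.3 and 21.8 CPM, and DHCR7 at 49.8, 47.2, 24.8 and 20.9 CPM. Lipid droplet genes were lower in the trend (camera, adjusted p = 0.0198 and, with an estimated correlation, adjusted p = 0.717), while PLIN2, a lipid droplet coat protein gene, was at 159.5 CPM in course 1 and 43.8 CPM in the parental library.

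The list of 13 mitochondrially encoded proteins was lower in the trend (camera, adjusted p = 0.0405 and, with an estimated correlation, adjusted p = 0.846), and this rested on course 5. All 13 members were lower in course 5 than in the parental library, with a median log2 ratio of -0.63. The medians were 0.03 in course 1 and 0.18 in course 3, without course 5 the list's direction turned, and without course 1 its call was lost as well. MT-CO3, a subunit gene of cytochrome c oxidase, stood at 14603, 10797, 14530 and 7838 CPM in the parental, course 1, course 3 and course 5 libraries. The mitochondrial share of gene counts was 13.57%, 14.36%, 15.11% and 9.22% (exact 95% interval 9.21 to 9.22% for course 5, which covers counting error only). The protein-coding part of it was 11.47%, 10.13%, 12.56% and 7.25%, and the ribosomal RNA part 2.09%, 4.23%, 2.55% and 1.97%. Reads aligned to several places took 13.86%, 15.39%, 14.24% and 21.33% of all reads, so course 5 differed in this share too. Lists of nuclear-encoded oxidative phosphorylation, mitochondrial DNA maintenance, fatty acid oxidation, fatty acid synthesis and cholesterol uptake did not pass camera in either comparison, although the desaturase gene FADS2 stood at 47.7, 32.1, 12.6 and 6.32 CPM.

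Cytosolic ribosomal protein genes were higher in the DMSO libraries in the pooled test (camera, adjusted p = 2.75e-09) and in the trend (camera, adjusted p = 1.3e-11). With an estimated correlation neither call held (adjusted p = 0.976 and adjusted p = 0.717). All 45 tested members were higher than in the parental library in courses 3 and 5 and 43 were in course 1, by medians of 0.28, 0.39 and 0.63 log2 units in courses 1, 3 and 5. In the trend, 32 members passed adjusted over the list alone and 0 over all genes. RPL13 was at 1018, 1674, 1864 and 2345 CPM. p53 targets were higher in both tests (camera, adjusted p = 0.03 and adjusted p = 0.000353), by medians of 0.26, 0.07 and 0.57. Both calls were lost with an estimated correlation (adjusted p = 0.976 and adjusted p = 0.717) and without course 5, where 4 lists of the pooled comparison and 14 of the trend passed. In course 3, 13 of 23 members were higher and 10 lower. Among the members were ZMAT3 at 18.6, 18.3, 40.4 and 65.8 CPM and GADD45A at 6.32, 8.54, 11.8 and 18.5 CPM.

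Proliferation genes were lower. All 24 mitotic genes were lower in courses 3 and 5 and 23 were in course 1, by medians of -0.25, -0.54 and -0.75 log2 units, and the list passed in the pooled test (camera, adjusted p = 1.1e-06) and the trend (camera, adjusted p = 2.02e-07). Neither call held with an estimated correlation (adjusted p = 0.976 and adjusted p = 0.717). DNA replication genes were lower in the pooled test (camera, adjusted p = 1.98e-08 and, with an estimated correlation, adjusted p = 0.976), by medians of -0.91, -0.56 and -0.55, with CDC6 at 42.6, 16.5, 21.9 and 23.7 CPM. They did not pass in the trend (camera, adjusted p = 0.0584), although they did at a mean of at least 5 CPM and without course 1 or course 5. Neutrophil granule genes were lower in both tests (camera, adjusted p = 0.0327 and adjusted p = 0.0143), and both calls were lost with an estimated correlation (adjusted p = 0.976 and adjusted p = 0.717). The medians were -0.37, -0.04 and -0.72, and 7 of 17 members were higher than in the parental library in courses 1 and 3. The list's summed level was 1639 CPM in the parental library and 2113 CPM in course 1, while the cathepsin G gene CTSG was at 209.8, 70.9, 83.3 and 90.9 CPM. Without course 5 the pooled call of the neutrophil list was lost, among 4 lists that passed. The directional test of fry called 0 of the 30 lists in either comparison, with a smallest adjusted p of 0.63 in the pooled comparison and 0.0927 in the trend. Its mixed test, for change in either direction, called 1 list in the pooled comparison, glutathione and NRF2 targets (adjusted p = 0.0131), and 9 in the trend. The 9 were p53 targets (adjusted p = 0.00645), crosslink and mismatch repair (adjusted p = 0.0151), interferon response, lymphoid, fatty acid synthesis, lipid droplet, mitotic, drug transporter and epithelial genes.

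The glycolysis and the amino acid stress lists had opposite signs in course 1 and the later courses. Genes of glycolysis and hypoxia had a median log2 ratio to the parental library of 0.77 in course 1, -0.65 in course 3 and -0.97 in course 5. Amino acid stress and unfolded protein genes had -0.92, 0.76 and 0.99. The medians of both lists lay beyond those of all 10000 matched random lists in all 3 courses. TRIB3 was at 60.0, 28.7, 149.7 and 294.1 CPM, and PKM at 860.0, 996.5, 451.5 and 356.6 CPM. Both lists passed in the trend at the preset correlation (camera, adjusted p = 4.56e-07 for glycolysis and hypoxia, adjusted p = 0.000176 for amino acid stress), and neither did with an estimated correlation (adjusted p = 0.717).

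**Figure D3:**
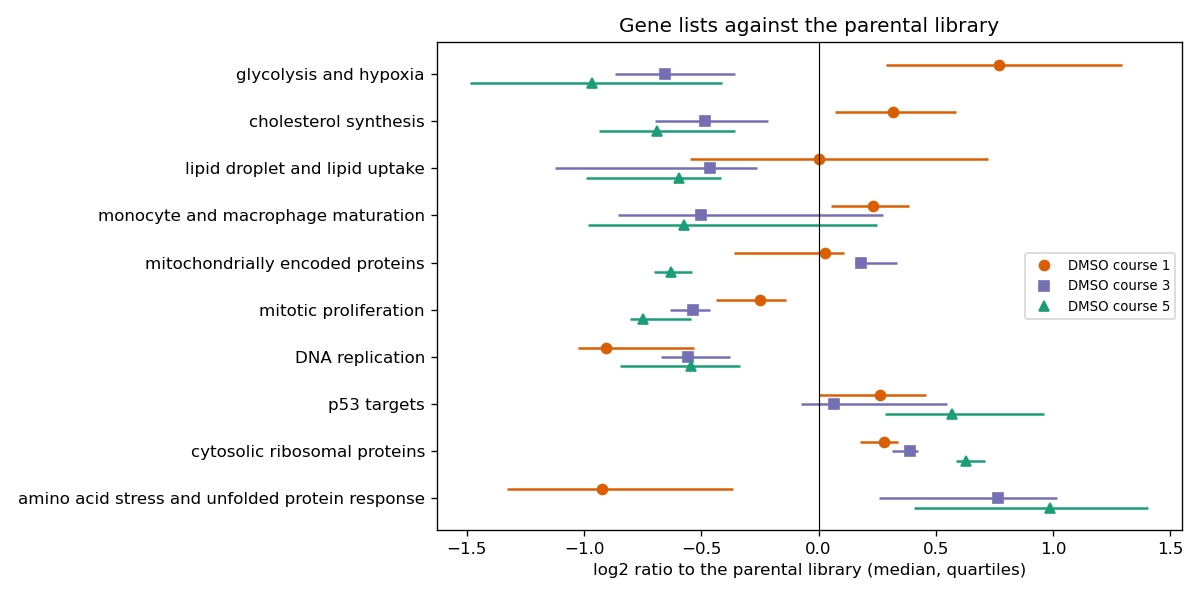
Median (point) and quartiles (line) over the tested members of 10 gene lists of the log2 ratio to the parental library (horizontal axis), in DMSO courses 1 (circles), 3 (squares) and 5 (triangles). Glycolysis and hypoxia genes lie at 0.77 in course 1 and -0.97 in course 5, and amino acid stress genes at -0.92 and 0.99.

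Inflammatory cytokine genes were lower in the trend (camera, adjusted p = 0.0348 and, with an estimated correlation, adjusted p = 0.717), with ICAM1 at 35.5, 43.7, 13.5 and 10.6 CPM. Monocyte maturation genes (medians 0.23, -0.50 and -0.57 in courses 1, 3 and 5) did not pass, and the proteoglycan gene VCAN among them stood at 3.97, 4.62, 43.3 and 52.3 CPM. Lists of the leukemia stem programme, interferon response, immediate early genes, heat shock, glutathione and NRF2 targets, crosslink and mismatch repair, drug transporters, replication-dependent histones and antigen presentation passed camera in neither comparison. Antigen presentation could hardly be measured, since the HLA genes and their neighbours on chromosome 6 are listed at or near 0 counts in every library. The heat shock gene HSPA1A was at 0 counts too, and the heat shock list was tested on 12 of its 14 genes. Among markers of other cell types, epithelial (camera, adjusted p = 0.0198) and lymphoid (camera, adjusted p = 0.00168) lists were lower in the trend and not with an estimated correlation (adjusted p = 0.717), from 5 and 10 tested members. The epithelial call was lost without course 5, among 14 lists that passed. KRT18 was at 28.5, 11.7, 5.68 and 4.35 CPM, while MUC1 was higher in course 1 (53.9 CPM) than in the parental library (36.8 CPM). Erythroid and megakaryocytic as well as fibroblast and endothelial markers passed camera in neither comparison.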

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

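The tests on the chromosome 6 region, on the abundant transcripts of other cells, on all listed T and B cell markers, on IGKC and GNLY, and on translation factors and pseudogenes were chosen after the related values had been seen. The exact interval on the fibroblast and endothelial markers, and the limits by which lists with opposite signs were picked, were also added after the values were seen. The other tests of this part were written down before their result.

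The glycolysis and hypoxia list had a median log2 ratio to the parental library of 0.768 in DMSO course 1 and -0.966 in course 5, the amino acid stress list -0.924 and 0.988, and the cholesterol synthesis list 0.318 and -0.689. These were the lists of 30 with opposite signs and a median outside the central 95% of random lists in both libraries, and the difference between courses was not tested, with 1 library each. Reads aligned to several places made up 21.33% of the course 5 reads against 13.86% in the parental library, a signal outside the gene counts. Whether transcript length or GC content bears on the higher ribosomal protein genes of course 5 was not tested. On reads shared with pseudogenes, translation factor genes had a median log2 ratio of 0.62 in course 5 against 0.63 for ribosomal protein genes. Processed pseudogenes of any gene took 2.79% of gene counts in course 5 against 2% in the parental library. Those of ribosomal proteins were not counted apart, so these values do not decide whether shared reads matter.

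DMSO courses 1 and 5 lay the farthest apart. Removing a trend on GC content and transcript length left 0.97 of the SD over genes (bootstrap interval 0.965 to 0.974). Poisson counting gave 0.077 of it, so the tables argue against both as the cause. Removing chromosome medians left 0.99 (0.988 to 0.992), so shifts of whole chromosomes made up little of the distance. A gain or loss in part of the cells could hardly have lowered the SD to the level set, so it is not excluded. Chromosome 19 (826 genes) had the median farthest from that of all genes, at -0.27 log2 units in course 5 over course 1. For cells of another type, the criterion set beforehand was met by all 4 lists: 2 of 3 erythroid and megakaryocytic markers (a share of 0.667), 4 of 7 lymphoid, 2 of 4 epithelial and 4 of 8 fibroblast and endothelial markers were at least 2-fold higher in course 1. The highest of 8 abundant transcripts of erythroid, epithelial or stromal cells (COL1A2) reached 0.093 CPM in the 2 libraries. Markers outside the 8 were higher, such as COL1A1 (2.51 CPM in course 1) and KRT18 (11.68), so the 8 alone do not settle epithelial or stromal cells. Against mature B cells, a share of 0.111 of 9 listed markers reached 1 CPM (exact interval 0.003 to 0.482). For T cells the share was 0.2 of 10 markers (0.025 to 0.556), with TRAC at 71.27 and 60.91 CPM in courses 1 and 5. CD3E, CD3G, CD2, CD5 and TRBC1 were at 0 in both, which argues against T cells, although CD7 was at 1.3 and 0.461 CPM. Plasma or NK cells stay open, with IGKC at 2.25 and GNLY at 1.09 CPM in course 1 against 0.07 and 0.2 in course 5. Both were higher in the parental library (6.47 and 5 CPM). NKG7 was at 101.49 CPM in course 1, but at 64.86, 65.13 and 51.65 in the parental, course 3 and course 5 libraries. It therefore does not single out course 1. A different state of the cultures stays open and is taken up among the other observations, and the number of courses is confounded with it.

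CDX2, BARX1 and other genes were far lower in all 3 DMSO libraries. Of 9 detected fibroblast and endothelial markers, a share of 0.111 was at least 2-fold higher in the parental library than in each DMSO library, under the 0.25 set beforehand as speaking against such cells, and the exact interval of 0.003 to 0.482 holds 0.25 but not the 0.5 they would need. The highest of the 8 abundant transcripts was 0.101 CPM in the parental library (COL1A2), which argues against cells rich in those transcripts. Markers outside the 8 were higher there, such as COL1A1 at 3.14 and KRT8 at 11.63 CPM, so the 8 alone do not settle epithelial or stromal cells. The epithelial marker KRT18 was at 28.5 CPM there against 11.68, 5.68 and 4.35 in the DMSO libraries. A share of 0 of the 9 listed mature B cell markers reached 1 CPM (exact interval 0 to 0.336), which argues against mature B cells there. For T cells the share was 0.2 of 10 markers (0.025 to 0.556), which alone does not decide. TRAC was lower in the parental library (48.04 CPM) than in courses 1, 3 and 5 (71.27, 81.5 and 60.91). CD2, CD5, TRBC1 and LCK were at 0 in the parental library. These values argue against T cells there. On the other side, CD3D was at 4.108 CPM there against 0.557, 0.06 and 0.088. CD3E and CD3G were at 0.152 and 0.034 CPM there and at 0 in the DMSO libraries. Plasma or NK cells stay open, since IGKC was at 6.47 CPM (2.25, 0.24 and 0.07 in courses 1, 3 and 5) and GNLY at 5 (1.09, 1.75 and 0.2). Of the 65 lower genes a share of 0.277 had another within 2 Mb, above the 95th percentile of 0.262 of random sets and below the 0.5 that a loss of chromosome segments would need, so that loss stays open, as do a subpopulation of the line in the parental culture and a change with passage, which were not tested.

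Of 182 protein-coding genes between 29 and 34 Mb of chromosome 6 (GENCODE release 29 positions), 165 or 90.7% had fewer than 10 reads over the 4 libraries, against 31.5% of the other protein-coding genes. TUBB, FLOT1 and CLIC1, which nearly all cells express, had 0 reads. Of 12 broadly expressed genes in 2 other regions for which the reference holds alternate haplotypes, a share of 0.5 had fewer than 10 reads (exact interval 0.211 to 0.789). RPS9, TSEN34 and PLEKHM1 with 0 reads were among them. Of the rest, KANSL1 had 10 reads, TFPT 19, LENG8 22 and PRPF31 64, while MBOAT7 had 1307 and CNOT3 2577. This just reaches the level set for reads lost as not unique on alternate haplotype copies, which may be the cause. The 12 genes were listed after other genes of such regions had been seen at 0 reads, so the share is no independent test. A loss of the chromosome 6 region alone would not account for the empty genes elsewhere, but the share does not exclude it. The build behind the alignment is uncertain.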

How the results depend on the processing

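The counts of genes past the test depended on the tool and on single libraries. Against 0 in edgeR, DESeq2 called 209 genes in the pooled comparison and 888 in the trend, and edgeR with no filter called 13 and 134. Leaving out 1 library gave 25 to 1578 genes in the pooled comparison and 5 to 3642 in the trend, the high values without course 1 and without the parental library. RLE size factors, limma-voom, a filter at a mean of 5 CPM and a slope per rank gave 0. The cause was not tested, except that leaving out course 1 keeps only the nearest pair of DMSO libraries to measure the spread. The 5 lists of the pooled comparison and the 12 of the trend became 0 and 0 with an estimated correlation. They became 0 and 0 with fry's directional test, counted as an alternative only after seeing the data. At a mean of at least 5 CPM, camera at the preset correlation called 7 of 25 lists in the pooled comparison and 11 in the trend. Nuclear-encoded oxidative phosphorylation and crosslink and mismatch repair joined the pooled calls. DNA replication joined the trend, and the epithelial and lymphoid lists had too few members left. Leaving out a library gave 4 to 11 lists in the pooled comparison and 12 to 14 in the trend. Without course 5 neutrophil granule genes and p53 targets were lost in the pooled comparison, and mitochondrially encoded, epithelial and p53 genes in the trend.

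Counts of genes at least 2-fold apart in courses 1, 3 and 5 (845, 490 and 844) moved with the minimum level and fold. They were 1430, 1045 and 1571 at a mean of at least 1 CPM, 477, 181 and 393 at 20 CPM, 2846, 1399 and 2489 at 1.5-fold and 172, 178 and 331 at 3-fold. At a mean of at least 50 CPM the distances of the parental library to courses 1, 3 and 5 were 0.508, 0.363 and 0.514, and those of courses 1 and 3, 1 and 5, and 3 and 5 were 0.544, 0.734 and 0.259. Fewer low genes enter at that level, and the nearest and farthest pairs were as before. For 57 named genes, 171 log2 ratios per scaling were recomputed, an alternative chosen after seeing the data. Of these 171 stayed within their counting interval with RLE and 156 with total CPM, and 0 turned sign among those 2-fold apart. No paired analysis was possible because each course has 1 library and the parental library carries another replicate number. Depth limits genes such as CDX2 in course 5, where 0 counts give only a bound.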

Other observations

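The hypothesis of this part was put to genes outside the lists tested first. Those genes were chosen after the first lists had been seen to differ, and before their own values were seen. The test that leaves these genes out was chosen after their values were seen, with its limits set before its own result.

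A candidate explanation for the distance between DMSO courses 1 and 5 is a different oxygen and amino acid state at harvest, with further hypoxia-induced genes lower and further ATF4 targets higher in course 5. Of 24 further hypoxia genes, 20 were lower, with a median log2 difference of -1.271, below all 10000 matched random lists, and of 19 further ATF4 targets 19 were higher, with a median of 1.94, above all 10000. These genes belong to the programmes already seen to differ and tend to follow them, so the values do not test whether such a state accounts for the distance. Without the 96 members of the 4 lists among the 10710 genes, the SD kept 0.971 of its size (bootstrap interval 0.959 to 0.981). Most of the distance thus lay in other genes. So few genes could hardly have lowered the SD to the level set, so this value does not test the explanation. With 1 library per course, a state at harvest cannot be separated from an effect of the courses or of passage.

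The order course 1, parental, course 3, course 5 was the 1 order of 12 that called genes (184). Across 10710 genes the difference of course 5 from course 3 and that of the parental library from course 1, which share no library, correlated with Pearson's r of 0.311 and Spearman's rho of 0.364. In the other pairings that share no library, course 5 minus parental against course 3 minus course 1 gave 0.604 and 0.535, and course 3 minus parental against course 5 minus course 1 gave 0.457 and 0.357. Genes are not independent replicates, so these values describe the 4 libraries only.

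The translation factor list, added after the data were seen, had medians of 0.06, 0.33 and 0.62 log2 units above the parental library in courses 1, 3 and 5, against 0.28, 0.39 and 0.63 for the ribosomal protein genes.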
